A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

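The data are 10 two-colour arrays of Saccharomyces cerevisiae, 1 for each hour from 1 to 10. Per the labels, channel 1 held filamentous-form RNA of that hour and channel 2 held yeast-form RNA. The deposited table holds 1 log2 ratio per open reading frame and array. The scanner, the dyes, any dye swap, the background correction, the normalization, the array design and the strain background are not given in the sources used here. The log base was settled from the values. With base 2, 98.5% of the deposited ratios were whole ten-thousandths within a tolerance of 0.02, against 9.73% with base e and 9.20% with base 10. Taking the values as log2, 99.7% of their log10 equivalents were whole thousandths within 0.1. The direction of the ratio is likely filamentous over yeast form but not stated, and any centring by the authors stays unknown. The array medians, with exact zeros left out, were between 0.12 and 0.39.

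The table has 6292 open reading frames and 62920 values, of which 3324 (5.28%) are exactly 0. Each of the 10 neighbouring steps of the scale held 82.9 values on average, so exact zeros were taken as missing. That choice was made after the values were seen, and the analysis was repeated with zeros kept. Systematic names were matched to a gene table of the RefSeq assembly R64, used for names and overlaps only, and 5792 names matched while 500 did not. Unmatched names were kept as in the file. Of the genes tested, 4858 had a standard symbol. DUR1,2 and ARG5,6 were matched to that table without their comma. Spot intensities are not used here, so signal over background is unknown.

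Each array was centred on its median. Genes with at least 8 of 10 values were tested (5775 genes, of which 4956 had all values). With limma 3.58.1 in R 4.3.3, lmFit and eBayes were run on the log2 ratios with an intercept, a linear and an orthogonal quadratic term in hour. The intercept is the mean over hours and was tested against 0. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. P-values measure the scatter of 10 single arrays about a curve, which may be technical, since nothing in the labels says that the hours came from separate cultures. The SD printed beside a gene's mean is that of its values over hours and includes any trend.

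Before the data were examined, 26 gene lists, the tests, most alternatives and the rule for named genes were fixed. The rule took the 10 highest and 10 lowest genes past the threshold with the same sign on every array and a standard symbol, up to 4 members of each list with the smallest adjusted p, a fixed set of 10 genes, and the 8 and 6 extreme genes in each direction past the threshold for slope and curvature, of which there were none. A named member of the G2/M list is not reported here. Lists were tested with camera at a preset correlation of 0.01, on genes with all 10 values, and repeated with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way and compares them with no other gene. The test and the median of a list differed in sign for meiosis and G2/M genes (mean) and for the nitrogen, haploid and hypoxic lists (linear change), none of them called there.

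Alternatives covered scaling, filters, variance model, array weights, time model, averaging of adjacent hours, leaving out each hour, and thresholds. Alternatives on exact zeros, odd and even hours, hours 1 and 2 together, log2 or inverse hour, scaling of the spread and quantile normalization for lists, the estimated correlation on each scaling and between odd and even hours, list counts and odd and even means without each hour, the comma of gene names and the exact permutation of 14400 orders of hours were added after the data were seen. The limma code was tested on simulated arrays of 5775 genes with 200 changed genes. Mean shifts of 0.5 were recovered for 1.7%, shifts of 1 for 65.9% and shifts of 2 for 95.3% of changed genes, with 1.18%, 4.35% and 6.96% of calls false. The simulated noise was independent, without odd and even clusters. In the data 2600 genes passed for the mean, and the adjusted threshold is more lenient where more genes pass. These shares therefore do not describe the data. A list of 20 independent genes with a slope of 0.1 per hour was recovered in 20 of 20 simulations, with 0 of 500 tests of unchanged lists called. Genes of several real lists were correlated, with an estimate of 0.24 for ribosomal proteins and 0.53 for glycolysis. These counts therefore do not describe the data either. With the hours of the real arrays shuffled, camera at the preset correlation called a median of 3 lists for a linear change. Figures were drawn with matplotlib 3.10.9.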

Results

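Gene expression was followed in wild-type diploid cells of budding yeast, Saccharomyces cerevisiae, over the first 10 hours after a change of growth form. Cells growing in the yeast form in SHAD, a liquid medium rich in glucose and ammonium, were moved to SLAD, an agar medium low in ammonium on which diploids grow as filaments. Each of the 10 arrays set RNA from filamentous-form cells of 1 hour, from hour 1 to hour 10, beside RNA from yeast-form cells on the same array. No hour had a second array, so the scatter of a gene about a smooth curve over the hours was the only measure of error, and this number of arrays limits the precision. Whether 1 yeast-form extract served all arrays is not stated in the labels. It is counted as 1 control, and a ratio against 0 leaves out the control's own spread and any dye bias of single genes. Ratios are written as filamentous over yeast form, which is likely but not stated in the labels. Its basis is the order of the channels in the labels and the higher ratios of genes for poor nitrogen sources, a sign check chosen before the data were examined.

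Of 6292 open reading frames, 5775 had at least 8 values and were tested. The number of usable values per array ran from 5802 at hour 7 to 6063 at hours 2 and 4. All 45 pairs of arrays were positively correlated across genes, with Pearson's r of 0.52 ± 0.09 (SD over pairs) and a lowest value of 0.33. Genes are not independent replicates, so these values describe the arrays. Arrays of odd hours resembled each other, as did arrays of even hours. The mean r was 0.60 ± 0.05 over the 20 pairs of the same kind and 0.45 ± 0.06 over the 25 mixed pairs. The first principal component, with 27.9% of the variance, placed the 5 odd hours on one side and the 5 even hours on the other. The labels name no such batch, and values within odd and within even hours are given below for the counts of genes and for the lists called.

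**Figure D1:**
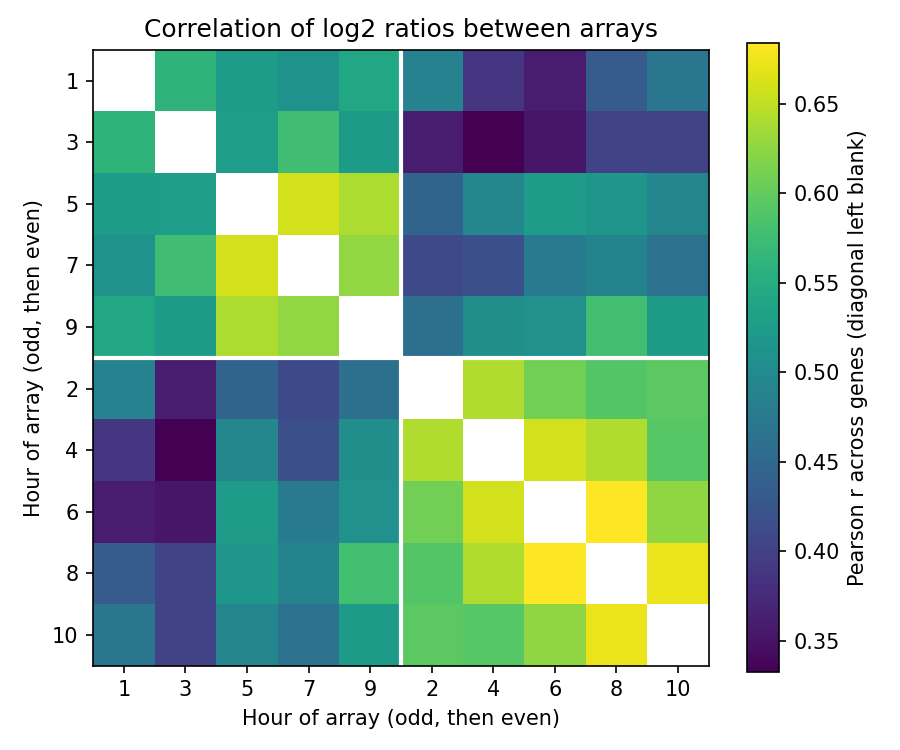
Pearson correlation across genes of centred log2 ratios for every pair of the 10 arrays, with the odd hours first and the even hours second on both axes and white lines between them. The blocks of odd with odd and even with even hold a mean r of 0.60, and the mixed blocks hold a mean r of 0.45.

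The first comparison asked which transcripts differed between filamentous-form and yeast-form cells over the 10 hours as a whole. DAL80, DAL7 and DAL4, of the list of nitrogen catabolite repression, were among the highest genes. DAL80, a GATA-type repressor of nitrogen genes, had a mean log2 ratio of 3.03 ± 1.16 (SD over hours, n = 10), DAL7, a malate synthase of allantoin breakdown, 2.94 ± 0.74, and DAL4, the allantoin permease, 2.75 ± 0.55. Among the lowest genes, ARN1, a siderophore transporter, was at -4.07 ± 0.70 (a 16.8-fold difference), BAP2, a permease for branched-chain amino acids, at -3.99 ± 1.01, and the cell wall mannoproteins HPF1, CWP2 and CCW12 at -3.23 ± 0.63, -3.09 ± 0.72 and -3.06 ± 0.47.

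In the limma fit, 1307 genes were higher and 1293 lower at an adjusted p under 0.05, and 494 and 596 of these differed at least 2-fold. The ratio lay above 0 on every array that measured the gene for 562 of the higher genes and below 0 for 823 of the lower ones. Arrays were centred on their medians, which were deposited at 0.12 to 0.39 with a mean of 0.30. On the deposited scale 2243 genes were higher and 885 lower, so that 71.7% of calls were higher ratios in place of 50.3% (28.3% in place of 49.7% with the direction of the ratio turned), and every change below is relative to the array median. With odd hours alone 862 genes were higher and 957 lower, and with even hours alone 1223 and 1367. Of the 1319 genes that passed in both sets, 1213 had the same sign and 106 had opposite signs.

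Among genes with a standard symbol, the others of the 10 highest that kept their sign on every array were YCT1, a cysteine transporter, at 3.34 ± 1.12, ZTA1, a quinone oxidoreductase, at 3.19 ± 0.78, REV1, a translesion DNA polymerase, at 2.97 ± 0.53, and ICY1 at 2.82 ± 0.75. They were followed by CUP1-2, a copper metallothionein with a near-identical second copy, at 2.81 ± 0.52, PCF11, an mRNA cleavage factor, at 2.77 ± 0.91, and RAV1, an assembly factor of the vacuolar proton pump, at 2.58 ± 0.62. The other lowest genes were SRL1, a cell wall mannoprotein, at -3.21 ± 0.94, ASC1, a ribosome-associated protein whose gene overlaps that of a small nucleolar RNA, at -3.05 ± 0.64, RPP0, a protein of the ribosomal stalk, at -2.99 ± 0.56, ENB1, a siderophore transporter, at -2.88 ± 0.82, and RIB4, an enzyme of riboflavin synthesis, at -2.85 ± 0.29. All 20 of these genes had 10 values, and their limma adjusted p-values ran from 1.0e-07 for RIB4 to 8.1e-05 for DAL80. Because these 20 genes were chosen for the same sign on every array, their means of odd and of even hours share that sign by construction. The odd and even means were 4.13 and 2.54 for YCT1 and -2.66 and -3.76 for SRL1.

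A set of 10 genes tied to filamentous growth and to nitrogen was chosen before the data were examined. GAP1, the general amino acid permease, was higher by 1.75 ± 0.33, PHD1, a transcription factor of filamentation, by 1.26 ± 0.59, and MEP2, an ammonium permease and sensor, by 1.15 ± 0.45. CLN1, a G1 cyclin, was higher by 0.87 ± 1.09 (adjusted p = 0.020 in limma), a call lost without hour 5 (adjusted p = 0.052), without hour 6 (adjusted p = 0.052) and with odd hours alone (adjusted p = 0.23). FLO11, the adhesin of filaments, had a mean of 0.63 ± 0.88 and did not pass (adjusted p = 0.080). Its mean was 1.06 over odd hours and 0.20 over even hours (0.0066 without hour 2), and it passed on the deposited scale (adjusted p = 0.011), without hour 8 (adjusted p = 0.034), with adjacent hours averaged (adjusted p = 0.035), with odd or even hour as a term (adjusted p = 0.0495) and with odd hours alone (adjusted p = 0.0489). TEC1, a filamentation transcription factor, had a mean of 0.87 ± 1.27 (adjusted p = 0.088), made of -0.09 over odd and 1.83 over even hours (the odd mean was 0.05 without hour 3 and 0.08 without hour 7), and passed with even hours alone (adjusted p = 0.0080), with odd or even hour as a term (adjusted p = 0.0071), on the deposited scale (adjusted p = 0.026), with adjacent hours averaged (adjusted p = 0.033) and with array weights (adjusted p = 0.049). STE12, its partner in transcription, had a mean of -0.11 ± 1.00 (adjusted p = 0.79) that rested on hour 2, at 2.62. Without hour 2 it was lower, at -0.42 (adjusted p = 0.027), and so it was with odd hours alone, at -0.65 (adjusted p = 0.031), while the mean of even hours, 0.43, was -0.12 without hour 2. PGU1, FLO8 and the mitotic cyclin CLB2 had means of 0.21 ± 0.42, -0.01 ± 0.41 and 0.02 ± 0.53 (n = 9 for CLB2) and did not pass in limma, with adjusted p-values of 0.18, 0.94 and 0.94. On the deposited scale PGU1 had a mean of 0.51 and passed (adjusted p = 0.0047).

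A further question was whether groups of genes, fixed as 26 lists before the data were examined, differed together. All 14 measured genes of glycolysis and fermentation were lower, with a median of -1.68 (11 of 14 on the deposited scale, with a median of -1.39). Examples are ENO1, an enolase, at -2.34 ± 0.52, TDH2 and TDH3, glyceraldehyde-3-phosphate dehydrogenases, at -2.14 ± 0.49 and -1.88 ± 0.31, and PDC5, a pyruvate decarboxylase, at -1.91 ± 0.63. Among 23 genes of ergosterol synthesis 16 were lower and 0 higher, with a median of -0.72 (13 and 0 on the deposited scale, with a median of -0.42), led by ERG4 at -2.39 ± 0.59, ERG3 at -2.03 ± 0.55, HMG1 at -1.85 ± 0.66 and ERG11 at -1.69 ± 0.59. In the iron regulon, genes of iron uptake, 11 of 16 were lower and 2 higher, with a median of -1.15 (11 and 3 on the deposited scale, with a median of -0.85). ARN1 and ENB1 belong to it, as do FET3, a multicopper oxidase of iron uptake, at -2.55 ± 0.46, and SMF3, a vacuolar metal transporter, at -1.96 ± 0.32. Among 15 genes of cell separation and mitotic exit 10 were lower and 1 higher, with a median of -1.06 (8 and 3 on the deposited scale, with a median of -0.77). The lowest were DSE2, a daughter-specific wall enzyme, at -2.82 ± 0.66, PRY3 at -2.43 ± 0.53, and CTS1, the chitinase of cell separation, at -2.18 ± 0.39.

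Among 133 cytosolic ribosomal protein genes 64 were lower and 12 higher, with a median of -0.34. On the deposited scale the median was -0.04, with 43 lower and 29 higher. RPL4B was at -2.75 ± 0.68, RPP2A at -2.11 ± 0.45 and RPL1A at -1.82 ± 0.49. Many ribosomal protein genes, like those of glycolysis and the histones, have near-identical copies whose signals an array can mix. Ribosome biogenesis factors went the other way, with 30 of 76 higher, 7 lower and a median of 0.38 (41 and 6 on the deposited scale, with a median of 0.67). DBP6, a helicase, was at 0.90 ± 0.34, NOP10 at 0.88 ± 0.34 and UTP10 at 0.77 ± 0.33, while TIF6, a factor of the large subunit, was at -1.65 ± 0.65. Of 29 genes of nitrogen catabolite repression, which cells keep off when ammonium is plentiful, 17 were higher and 6 lower, with a median of 0.79 (19 and 5 on the deposited scale, with a median of 1.08). This list was also a basis for the direction of the ratio and is no independent evidence of it. DAL2, an allantoin-degrading enzyme, was at 2.42 ± 0.60. The 6 lower genes, named after their values were seen, were VID30 at -2.16, the ammonium permease MEP3 at -1.86, the asparaginase ASP3-1, which has near-identical copies, at -1.70, the allantoate permease DAL5 at -1.07, the arginase CAR1 at -0.93 and the urea permease DUR3 at -0.57.

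These 7 lists passed limma's camera test for the mean against all other genes, with adjusted p-values from 1.2e-06 for glycolysis to 0.044 for nitrogen catabolite repression. None was called with an estimated correlation, where the adjusted p was 0.30 for the iron regulon, 0.59 for ribosomal proteins and 0.37 for each of the other 5 lists. The rotation test fry, which makes no comparison with other genes, called 16 of the 26 lists. The nitrogen list was also not called without hour 9 (adjusted p = 0.051), on the deposited scale (adjusted p = 0.13), with arrays scaled to equal spread (adjusted p = 0.051), after quantile normalization (adjusted p = 0.054), or with DUR1,2 left unmatched (adjusted p = 0.055). Adjusted over the list alone, the members higher and lower were 0 and 14 for glycolysis, 0 and 16 for ergosterol, 3 and 11 for iron, and 2 and 10 for cell separation. They were 13 and 64 for ribosomal proteins, 31 and 7 for ribosome biogenesis, and 19 and 7 for nitrogen catabolite repression. The list medians of means within odd and within even hours were -1.49 and -1.80 for glycolysis, -0.70 and -0.84 for ergosterol, -1.35 and -1.02 for iron and -0.80 and -1.19 for cell separation. They were -0.28 and -0.41 for ribosomal proteins, 0.28 and 0.51 for ribosome biogenesis, and 0.77 and 0.87 for nitrogen catabolite repression.

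**Figure D2:**
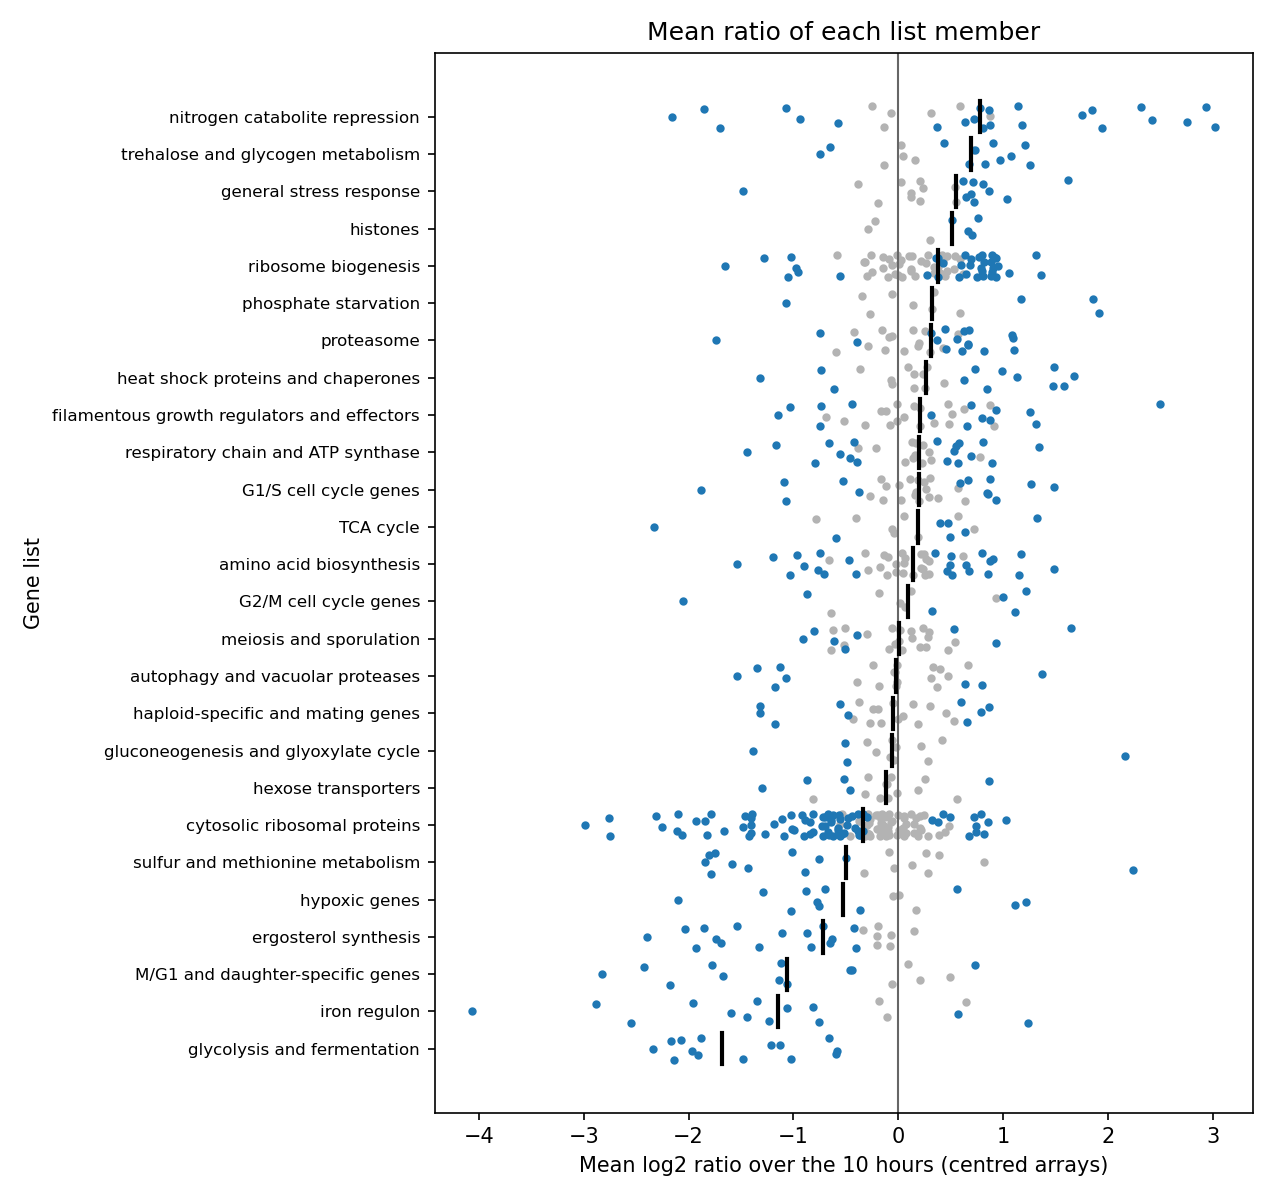
Mean log2 ratio over the 10 hours (horizontal axis) of every measured member of the 26 gene lists (vertical axis), with arrays centred. Blue points passed an adjusted p under 0.05 in limma, grey points did not, vertical offsets are for legibility, and black bars are list medians, which run from -1.68 for glycolysis to 0.79 for nitrogen catabolite repression.

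The other 19 lists did not pass camera for the mean. Of 33 regulators and effectors of filamentous growth 9 were higher and 5 lower, with a median of 0.21 (17 and 3 on the deposited scale, with a median of 0.51). KSS1, the MAP kinase of filamentation, was at 2.50 ± 0.42 and on the higher side on 10 of 10 arrays, while the kinase STE20 and the repressor SFL1 were at -1.03 ± 0.33 and -1.15 ± 0.31. General stress genes had 9 of 20 members higher and 1 lower (median 0.55; 4 and 2 without hour 1, median 0.35), with HSP12 at 1.62 ± 0.89 and GRE1 at -1.48 ± 0.42. Genes of trehalose and glycogen metabolism had 9 of 16 higher and 2 lower (median 0.70; 5 and 2 without hour 1, median 0.38), and chaperones 9 of 22 higher and 3 lower (median 0.27), with FES1 at 1.68 ± 0.56 and AHA1 at 1.49 ± 0.49. The chaperone median was 0.18 without hour 2 and 0.48 without hour 3. Proteasome subunits had 14 of 32 higher and 3 lower (median 0.31), and histones 4 of 7 higher and 0 lower (median 0.52). In sulfur and methionine metabolism 10 of 19 were lower and 1 higher (median -0.49; 8 and 4 on the deposited scale, median -0.20), the higher one on the centred scale being the sulfate permease SUL1 at 2.24 ± 0.42, beside MET17 at -1.81 ± 0.44 and SAM1 at -1.75 ± 0.42. MET17 overlaps another annotated frame. The proteasome and sulfur lists also passed on the deposited scale (adjusted p = 0.037 each) and with exact zeros kept (adjusted p = 0.042 and 0.035). Neither did so with an estimated correlation, where the proteasome and sulfur lists had an adjusted p of 0.496 and 0.652 on the deposited scale and of 0.275 and 0.382 with zeros kept. Camera called 8 lists for the mean without hour 3, without hour 10 and without hours 1 and 2 together. It called 9 without hour 5 and 9 without hour 8, so lists outside the 7 passed in these settings too.

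Among hypoxic genes 3 of 14 were higher and 8 lower (median -0.53), with the wall mannoprotein TIR4 at -2.10 ± 1.17 and the ATP/ADP carrier AAC3 at 1.12 ± 0.79. Amino acid biosynthesis had 14 of 47 higher and 10 lower (median 0.14, but 0.09 without hour 3), with ARG3 at 1.48 ± 0.54 and HOM6 at -1.54 ± 0.30. The respiratory chain and ATP synthase had 10 of 30 higher and 8 lower (median 0.20), the TCA cycle 5 of 15 and 2 (median 0.19), and phosphate genes 3 of 11 and 1 (median 0.33). Genes of the G1/S phase had 8 of 31 higher and 5 lower (median 0.20), and those of G2/M 4 of 12 and 2 (median 0.09). Without hour 2 the G1/S median was 0.30, and the G2/M median was 0.03 without hour 1 and 0.18 without hour 3. Hexose transporters had 1 of 17 higher and 4 lower (median -0.11, but -0.09 without hour 1 and -0.18 without hour 3), with the low-affinity carrier HXT1 at -1.30 ± 0.37. Gluconeogenesis had 1 of 13 higher and 3 lower (median -0.06), the higher one being the malate synthase MLS1 at 2.17 ± 1.34. The lower ones were ACS1 at -1.39, MDH2 at -0.50 and IDP2 at -0.49, of which MDH2 and IDP2 did not pass on the deposited scale. Autophagy and vacuolar proteases had 3 of 22 and 5 (median -0.02), with the aminopeptidase LAP3 at 1.38 ± 0.51 and the vacuolar proteases PEP4 at -1.34 ± 0.87 and PRB1 at -1.13 ± 0.42. As markers of other cell types, haploid and mating genes had 4 of 23 higher and 5 lower (median -0.05) and meiosis and sporulation genes 3 of 28 and 5 (median 0.01). The haploid list was defined as genes that diploids keep off. Its members still passed in both directions, such as FUS2 at 0.66 and AGA2 at -1.32, beside 1307 higher and 1293 lower of all 5775 genes. A call on a single gene therefore does not show by itself that the gene is expressed. The balance of the list counts depends on centring. On the deposited scale the members higher and lower were 18 and 4 for the respiratory chain (median 0.50), 25 and 8 for amino acid biosynthesis (0.44), 14 and 3 for G1/S (0.51), 5 and 2 for G2/M (0.39), 8 and 1 for the TCA cycle (0.49), 6 and 1 for phosphate genes (0.62) and 4 and 6 for hypoxic genes (-0.23). They were 15 and 1 for general stress (0.84), 9 and 2 for trehalose and glycogen (0.99), 12 and 1 for chaperones (0.56), 21 and 1 for the proteasome (0.61) and 5 and 0 for histones (0.81). The balance turned for hexose transporters, with 2 and 1 (0.18), gluconeogenesis, with 4 and 1 (0.24), autophagy, with 6 and 5 (0.28), haploid genes, with 6 and 2 (0.25), and meiosis genes, with 4 and 2 (0.31).

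Between odd and even hours, camera called the TCA cycle (adjusted p = 0.022) and ribosomal proteins (adjusted p = 0.039), both lower in even hours, and neither with an estimated correlation (adjusted p = 0.956 each). The list medians of means within odd and within even hours had opposite signs in 3 lists, at 0.34 and -0.19 for the TCA cycle, -0.30 and 0.12 for gluconeogenesis and -0.25 and 0.23 for meiosis genes. They were 0.41 and 0.23 for general stress, 0.69 and 0.43 for trehalose and glycogen, 0.32 and 0.09 for the respiratory chain, 0.36 and 0.35 for the proteasome and -0.02 and -0.05 for autophagy. The TCA median of 0.19 was 0.10 without hour 2, 0.32 without hour 3 and 0.13 without hour 10. Without single hours the small medians of the haploid, meiosis, gluconeogenesis and autophagy lists changed sign.

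The second comparison followed the ratios from hour to hour. In several lists the median of hour 1 lay outside the range of hours 3 to 10, and in some that of hour 2 did too, while single genes did not pass. The median of general stress genes was 1.64 at hour 1 and 1.16 at hour 2, against 0.19 ± 0.17 (SD, n = 8) over hours 3 to 10. Genes of trehalose and glycogen metabolism went from 1.80 and 0.69 to 0.14 ± 0.21, and those of the respiratory chain and ATP synthase went from 0.84 at hour 1 to 0.04 ± 0.26, with 0.52 both at hour 2 and at hour 3. The median of the TCA cycle was 1.22 at hour 1 and 0.13 at hour 2, against 0.02 ± 0.33. Ribosomal protein genes went from -1.20 and -0.98 to -0.20 ± 0.13, and ribosome biogenesis from -0.58 and 0.09 to 0.47 ± 0.13. The division into hours 1 and 2 and later hours was chosen after the values were seen.

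For a linear change over hours, camera called 10 of the 26 lists. With odd or even hour as a term it also called amino acid biosynthesis (adjusted p = 0.030, but 0.735 with an estimated correlation as well). Ribosomal proteins (adjusted p = 6.0e-22) and ribosome biogenesis (adjusted p = 6.2e-06) had rising ratios. The lists of the respiratory chain, TCA cycle, iron regulon, autophagy and vacuolar proteases, general stress, trehalose and glycogen, gluconeogenesis and proteasome had falling ratios, with adjusted p-values from 5.8e-06 for the respiratory chain to 0.033 for the proteasome. None of the 10 was called with an estimated correlation, where the adjusted p was 0.081 for the respiratory chain, autophagy and general stress, 0.107 for ribosome biogenesis, the iron regulon and the proteasome, 0.111 for ribosomal proteins, 0.189 for the TCA cycle, 0.242 for trehalose and glycogen and 0.302 for gluconeogenesis. The estimated correlation of autophagy, general stress and the proteasome (-0.010, -0.0075 and -0.0081) lay below the preset 0.01. For these lists a stronger correlation is thus not what ended the calls. An exact permutation of the hours within odd and within even arrays, two-sided on the slope of the list median and run after the data were seen, also called none of the 26 (lowest adjusted p = 0.20, with raw p = 0.0082 for the iron regulon). Without hours 1 and 2, none of the 10 was called (lowest adjusted p = 0.18), while camera at the preset correlation alone called ergosterol synthesis upward (adjusted p = 6.0e-06) and amino acid biosynthesis downward (adjusted p = 0.00085), and the direction turned for ribosomal proteins, ribosome biogenesis, general stress and trehalose. Without hour 1 alone, 6 of the 10 calls were lost, with an adjusted p of 0.110 for ribosome biogenesis and the proteasome, 0.0998 for general stress, 0.908 for trehalose and glycogen, 0.244 for gluconeogenesis and 0.0646 for autophagy. The proteasome call was also lost without hour 2 (adjusted p = 0.068) and without hour 7 (adjusted p = 0.065), with arrays scaled to equal spread (adjusted p = 0.094) and after quantile normalization (adjusted p = 0.062), and the gluconeogenesis call without hour 9 (adjusted p = 0.096).

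Slopes of the list medians, in log2 per hour, had the same sign within odd and within even hours for 9 of these 10 lists. They were 0.12 and 0.05 for ribosomal proteins, 0.11 and 0.03 for ribosome biogenesis, -0.11 and -0.09 for general stress, -0.07 and -0.07 for the respiratory chain, -0.13 and -0.01 for the TCA cycle, -0.09 and -0.05 for the iron regulon, -0.13 and -0.03 for trehalose and glycogen, -0.18 and -0.01 for gluconeogenesis and -0.03 and -0.03 for the proteasome. For autophagy and vacuolar proteases they were -0.06 and 0.01. The 10 lists were picked by their linear change over these same arrays, so a shared sign is partly built in and is no independent evidence.

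**Figure D3:**
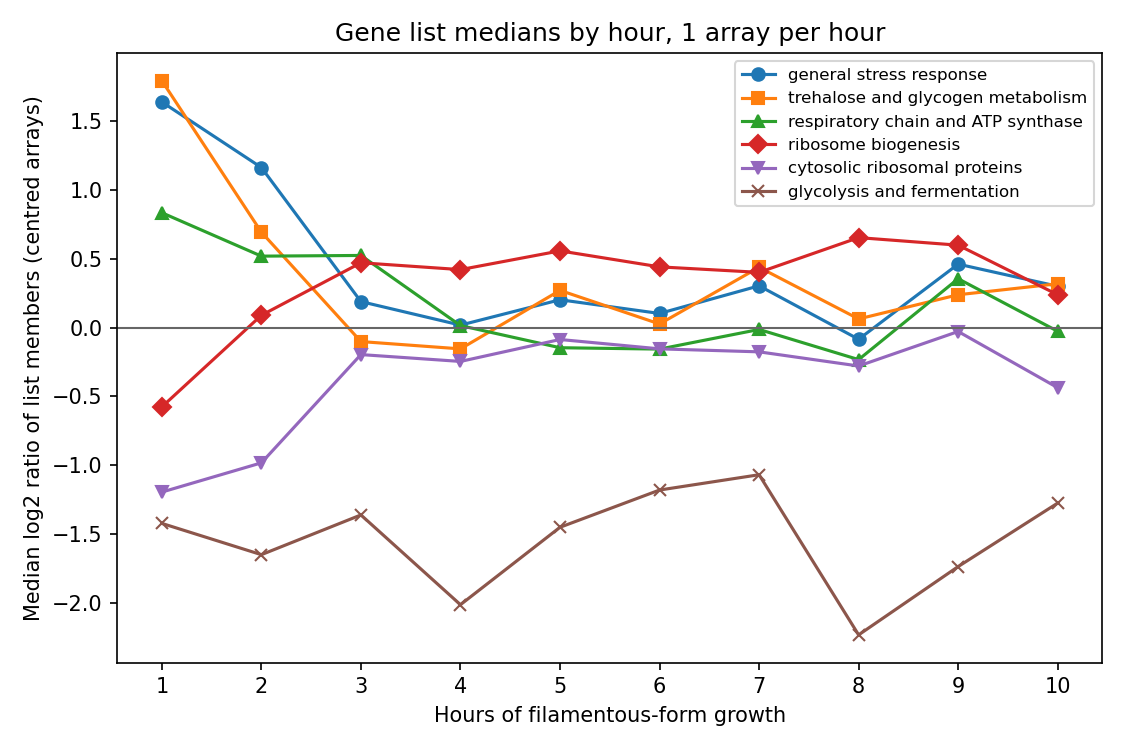
Median centred log2 ratio of 6 gene lists (vertical axis) at each hour of filamentous-form growth (horizontal axis), with 1 array per hour and no error bars because no hour was repeated. General stress genes stand at 1.64 and 1.16 at hours 1 and 2 and near 0.19 afterwards, ribosomal protein genes at -1.20 and -0.98 and then near -0.20, and glycolysis genes below -1 at every hour.

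No single gene passed for a linear change in the limma fit. The lowest adjusted p was 0.092, for the aconitase ACO1, whose ratio had a slope of -0.31 per hour, and CPP3, AAT2, an aspartate aminotransferase, and FIT2, a cell wall protein of iron uptake, followed at -0.39, -0.27 and -0.41 per hour (adjusted p = 0.0955 each). These 4 were named after their values were seen. At an unadjusted p under 0.05 there were 641 genes, where 288.75 would be expected by chance. Quantile normalization called 10 genes and a fit with the linear term only called 3. Adjusted over the list alone, 4 genes of the iron regulon, 3 of the TCA cycle, and 1 each of general stress, trehalose and gluconeogenesis passed. No gene passed in limma for curvature over the hours either, where 603 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.24. On simulated arrays with the real spread, independent noise and 200 changed genes, slopes of 0.1 per hour were recovered for 0% of changed genes, slopes of 0.2 for 15.9% and slopes of 0.4 for 75.6%.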

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

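The settings on exact zeros, odd and even hours, hours 1 and 2 together, the exact permutation of hours, equal spread and quantile normalization for lists, list counts without each hour and the comma of gene names were chosen after the data were seen. Counts of genes higher and lower moved by over 1.5 times in few settings. They were 2243 higher on the deposited scale, 850 higher at an adjusted p under 0.01, 494 higher and 596 lower with a mean of at least 1 also required, and 862 higher with odd hours alone. Without each hour in turn, 1175 to 1333 genes were higher and 1214 to 1285 lower. Without hours 1 and 2 together they were 1110 and 1172, with exact zeros kept as 0 they were 1450 and 1240, and with odd or even hour as a term 1490 and 1394. A linear change was called for 10 genes after quantile normalization and 3 with the linear term only. It was called for 0 genes in the other settings, as was curvature in all of its settings.

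Lists called for the mean went from 7 to 0 with an estimated correlation and to 16 with fry, and without each hour in turn from 6 to 9. Lists called for a linear change went from 10 to 0 with an estimated correlation, to 0 with the exact permutation of hours and to 2 without hours 1 and 2, both outside the 10, and without each hour in turn from 8 to 11. These counts can hide a turnover. Without hour 1, 8 lists were called although 6 of the 10 were lost, so lists outside the 10 were among them. Without hours 1 and 2 the direction turned, at raw p of 0.568 for ribosomal proteins, 0.779 for ribosome biogenesis, 0.832 for general stress and 0.310 for trehalose and glycogen.

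Among 127 named genes, sign changes occurred in genes not past the threshold. STE12 had a mean of 0.18 on the deposited scale and 0.43 with even hours alone, and without hour 2 the mean of even hours was -0.12. FLO8 had 0.28 on the deposited scale, 0.0528 with zeros kept and 0.225 with odd hours alone. TEC1 had -0.0857 with odd hours alone, a sign that turned without hour 3 or hour 7. CLB2 had -0.0172 with array weights, -0.000240 with the linear term only, -0.000794 with a cubic term, -0.00816 with a spline and -0.0698 with odd hours alone. Without each hour in turn, the mean of FLO8 ran from -0.103 to 0.0406 and the mean of CLB2 ran from -0.103 to 0.105. Over all settings of these genes, 3342 results kept their side of the threshold, 50 lost a call and 13 gained one. Mean array correlation was 0.51 with Spearman's method. The cause of these shifts was not tested, except where fewer arrays or a stricter threshold make calls rarer. Each ratio already pairs filamentous-form with yeast-form RNA on the same array, and with 1 array per hour there was no replicate within an hour. Spot intensities are not used here, so how far signal over background limits single genes is unknown.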

Other observations

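Tests chosen only after the result was seen are the counts of letter-suffix frames, the splits into odd and even hours, the shared missing spots, the cell cycle genes between odd and even hours, the single-copy glycolytic genes, the position of hour 2 and the orders of hours within odd and even arrays. Open reading frames whose systematic names carry a letter suffix, a class that includes gag and pol frames of Ty retrotransposons, were higher more often, and lower less often, than other frames. Of 185 tested, 78 (42.2%) were higher and 26 lower, against 22.0% higher among 5590 others (Fisher's exact test, two-sided, p = 1.8e-09). The share lower was 14.1% against 22.7% (Fisher's exact test, p = 0.0053), and with the direction of the ratio turned these shares change places. Ty frames are near-identical copies whose signals an array can mix, so they are not independent and these p-values are too small. The highest was YOR142W-B at 3.36 ± 0.99 (SD over hours, n = 10), and YPL257W-A was at 3.35 ± 0.44.

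Several genes, named after their values were seen, had far higher means in odd hours or in even hours. CIT1, the mitochondrial citrate synthase, had a mean of 2.21 over odd and -1.06 over even hours, SLK19, a kinetochore protein, 2.96 and -0.01, and RPB10, an RNA polymerase subunit, 2.07 and -0.70. GYP5 had -1.39 and 1.65, the glutaredoxin GRX3 -1.60 and 1.11, and HOT1, a transcription factor of osmotic stress, -0.76 and 2.07. With hour and its square in the limma fit, 116 genes were higher in even hours and 251 in odd hours at an adjusted p under 0.05.

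Without hour terms the odd and even split called 353 genes, and 1 of 100 splits of the 10 arrays into 5 and 5, the real one, gave as many, with at most 1 gene in the others. The split was picked from these same ratios, so this count restates the clusters and does not by itself exclude chance. Arrays of the same kind lacked ratios for the same spots. The phi correlation of missing values was 0.37 on average within odd or even hours and 0.17 between them, a difference of 0.206, above the highest of the other splits (0.0710 over 126 splits). Separate printings or hybridization batches of alternating arrays are thus a candidate explanation. A cell cycle in step was tested on 65 cell cycle genes, of which 3.08% were called against 6.39% of others, an odds ratio of 0.465 with a 95% interval of 0.0549 to 1.76, which leaves it open.

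Many transcripts listed as abundant had low mean ratios, and an intensity-dependent bias of the arrays may contribute to the glycolysis and sterol results. Spot intensities are not used here, so the abundance of these transcripts, those of the sterol list included, was not measured. Among 30 other abundant transcripts, listed before their ratios were examined as a set, 16 were lower, 5 were higher and 9 did not pass. Members of the 26 gene lists were left out of this set. Ribosomal proteins, left out in this way, had a median of -0.34, and of -0.04 on the deposited scale, far from the glycolysis median of -1.68. The median of the 30 was -0.446, with a 95% bootstrap interval of -1.24 to -0.0807 that spans -0.842, the level set at 50 percent of the glycolysis median. Paralog pairs whose signals an array can mix, such as TEF1 and TEF2 or EFT1 and EFT2, were drawn as separate genes. The interval is thus likely too narrow, and the bias cannot be told apart from a change in the cells. Among members of the 30 named after their values were seen, ACT1, actin, was at -2.52 ± 0.89 and PMA1, the plasma membrane proton pump, at -1.88 ± 0.49, while AHP1, a peroxiredoxin, was at 1.66 ± 0.43 and GPP1, a glycerol phosphatase, at 1.58 ± 0.23. Signal shared between paralogs cannot be the source for PGI1, TPI1 and FBA1, single-copy genes of which 3 of 3 were lower, at -1.22 ± 0.18, -1.02 ± 0.37 and -0.58 ± 0.39. All 14 list members were known to be lower before these were singled out, and for members with paralogs it stays open.

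The list shifts over hours rest on the first arrays, and chance order is not excluded. Over all orders of the hours, 4 of 100, the real one included, called as many as the 10 lists, with at most 11 in another order, but these ignore the odd and even clusters. With hours shuffled within odd and within even arrays, 6 of 100 did so, again with at most 11. The median number of lists called was 3 over each kind of shuffled order. Hour 1 lay outside the range of hours 3 to 10 in 10 of the 10 lists and hour 2 did so on the same side in 6, while hour 2 lay within it in 4 and leaving out hour 1 ended 6 of the calls, so the hour 1 array alone cannot be told apart from a shift over both hours. That range pools odd and even hours. Within even hours, hour 2 was above all later ones for the TCA cycle (0.13, against -0.01 at hour 10, the next highest) and the respiratory chain (0.52, against 0.01 at hour 4). It was not so for gluconeogenesis or autophagy. The 10 lists were picked by their slope over these same arrays, so an extreme hour 1 is partly built in. Among the 16 lists not called, hour 1 also lay outside the range of hours 3 to 10 in some. These were filamentous growth, chaperones, hexose transporters, amino acid biosynthesis, histones, ergosterol and phosphate genes. A wider spread of the first array is argued against by 9 of 10 calls that held after all arrays were scaled to equal spread. An early transient response to the change of medium stays open as a hypothesis, and no second culture was there to test it.

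For the mean over hours, 1 of 100 random sign turns of whole arrays, the real one, gave as many as 2600 genes, with 1169 at most in the others, which excludes chance only if the arrays are independent. The odd and even clusters put that in doubt, and turns of whole clusters are too few for a test. These turns also do not test the yeast-form RNA. If 1 extract served all arrays, which the labels do not state, its own deviation would appear on each of them.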
